A study of Mus musculus with 6 samples.

How the data were processed

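Droplet single-cell RNA sequencing was done on immune cells of C57BL/6 mice with experimental autoimmune encephalomyelitis, a mouse model of multiple sclerosis. Per the labels' protocols, disease was induced with myelin oligodendrocyte glycoprotein (MOG) in complete Freund's adjuvant and with pertussis toxin, and treatment was given at a clinical score of 3. The treatment was a dual microparticle formulation that carried either MOG, the disease antigen, or ovalbumin (OVA), an antigen unrelated to the disease. Inguinal lymph node cells were taken 2 days after treatment and sorted for T cell receptor beta, CD19, CD11c, and CD11b without CD11c, and the 4 sorted populations were mixed again in equal parts, with CD11b cells filling in where CD11c cells were short, to 10000 cells. Spinal cords were perfused, digested with collagenase, separated on Percoll and sorted for CD45, which all leukocytes carry. The day of the spinal cord samples is not given in the sources used here. The lymph node mixing fixes the balance of T, B, dendritic and myeloid cells, so shares between those populations were not compared in lymph node.

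The deposited values are unnormalised counts of unique molecular identifiers (UMIs) per gene and barcode, 1 matrix per library, made with Cell Ranger 3.1.0 per the file headers and per the submitters' processing notes. Those notes also name the mm10 mouse genome build and Seurat 4, without giving what Seurat did. The lowest UMI total of a barcode was 500 in 5 libraries and 501 in lymph node MOG replicate 2, so the smallest barcodes had been left out before deposit. The series design speaks of mice without tying each library to an animal. The p-values of genes and shares thus measure the spread between these libraries, which can hold technical as well as animal-to-animal variation. The camera p-values of gene lists compare a list's genes with the other genes. At the preset correlation they can be very small with few libraries and do not measure the spread between animals. Confidence intervals on counts and shares cover counting error only. The 31053 genes of the matrices were matched to GENCODE vM21 (GRCm38, the same assembly as mm10), from which coordinates were taken. Gene identifiers matched for 30934 genes, the symbol was also the same for 30468, and 119 found no match.

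Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. Doublets were scored with scrublet as run in scanpy 1.11.5. Its automatic threshold marked 0 barcodes in either spinal cord library and 18 in lymph node MOG replicate 1 (0.123%), so it had not worked there. The barcodes with the highest scores were instead removed in every library at a rate of 0.8% per 1000 barcodes. This took out 1767 barcodes from spinal cord MOG, 502 from spinal cord OVA, 1725 and 824 from lymph node MOG replicates 1 and 2, and 1114 and 213 from lymph node OVA replicates 1 and 2.

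Clusters were made per tissue from 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scikit-learn 1.9.0, Python 3.11.15), with a fixed seed. Markers for each class were fixed before the data were examined. A cluster was called X-like when at least 3 markers of that class were detected and at least 2 stood among its 30 top genes, with detection meaning a level at least 2 times that of the median cluster in at least 10% of cells. Several details of this scoring were settled after the clusters had been seen: the comparison with the median cluster, the ranking of competing names, the absence of a T cell subtype for dividing clusters, the check of the 10 leading genes for markers of another class, and the rule that a cluster with at least 95% of its cells from 1 library stays unnamed. Lymph node gave 30 clusters, of which 5 stayed unnamed and 4 of those were nearly all from 1 library. Spinal cord gave 24, of which 2 stayed unnamed. CD4, CD8 and regulatory (Treg-like) subtypes lie within the T-like class, so results in these classes are not independent of each other.

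In lymph node, counts were summed per library and class, and MOG (2 libraries) was compared with OVA (2 libraries) in 9 classes with at least 50 cells in each library. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with edgeR's filter on low counts and TMM normalisation, and Benjamini-Hochberg adjustment within each class at a threshold of 0.05. Fold changes are log2 of MOG over OVA, and each standard error is the fold change divided by the square root of the F statistic. Gene lists, 30 in all, were fixed before the data were examined and were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with adjustment over the lists of a class, and again with an estimated correlation. A list's median is taken over its tested members. Shares of cells were compared by exact two-sided permutation tests. With 2 libraries against 2 the smallest p such a test can give is 0.333, so no share could pass the threshold.

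In spinal cord, each treatment has 1 library, so there is no test, and no p-value is given. For classes with at least 100 cells in each library, the ratio of counts scaled to the library total (CPM) is given with an exact 95% interval from the binomial distribution of the UMIs of both libraries. Genes were described as differing when they reached 50 CPM in either library and the interval lay beyond a 2-fold difference. The same count was made between the 2 lymph node libraries of each treatment, as a measure of how far libraries of 1 group lie apart. A list's median log2 ratio, over members with at least 20 UMIs, was placed among the medians of 10000 random lists of equal size matched on expression in 20 bins. This percentile describes those libraries and is not a test. Shares carry exact Clopper-Pearson intervals (scipy 1.17.1, pandas 2.3.3), and shares of T-like cells with a UMI of a gene were computed after thinning each cell to 1000 UMIs. A share of 0 is given with the limit of 3 cells of the total that it allows.

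The rule for named genes was also fixed before the data were examined. In each lymph node class it takes up to 6 genes per direction with the largest fold among those that pass, or, where fewer than 4 pass, the 4 per direction with the smallest p. It asks for non-overlapping libraries and for 20 CPM in the higher group. In each spinal cord class it takes the 6 genes per direction whose interval lies farthest from 0, at 50 CPM or more. To these it adds the 4 members with the smallest p, or in spinal cord the largest absolute log2 ratio at 20 UMIs or more, of each list described, and a set of genes always reported: Foxp3, Il10, Ifng, Il17a, Csf2, Pdcd1, Lag3 and Ctla4 in T cell classes, and Cd274, Pdcd1lg2, Cd80, Cd86, Cd40, Il1b, Tgfb1, Arg1 and Apoe in antigen-presenting and myeloid classes. Immunoglobulin and T cell receptor segments, gene models without a name, ribosomal protein genes, mitochondrial transcripts, haemoglobins and sex-linked genes were left out of the first part of the rule. Always-reported genes too low to be tested in a class, such as Il10 and Il17a in lymph node, have no fold change there.

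The scripts were tested on simulated data. Where counts drawn from the lymph node libraries held genes changed by 2 on the log2 scale, edgeR recovered between 65.7% (dendritic-like) and 94.0% (CD8 T-like) of them, and for a change of 1 between 4.48% (dendritic-like) and 43.3% (CD4 T-like). It also called 6 to 20 unchanged genes per class, which made up between 4.97% (CD8 T-like) and 12.5% (monocyte/macrophage-like) of its calls. That share exceeded 5% in 8 of the 9 classes, so in the simulation the adjusted threshold of 0.05 let through more false calls than it names. Simulated libraries varied independently, while real libraries of the same number deviated together. The recovery and false-call rates therefore hold for the simulation and were not shown for the real fits. Alternatives fixed before the data were examined were DESeq2 1.42.0 with its size factors, edgeR with DESeq2's scaling, no filter on low counts, a replicate block, leaving out each lymph node library in turn, no doublet removal, a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial UMIs), Leiden resolutions 0.5 and 2, a lower level of 10 CPM, and thinning to 500 or 2000 UMIs or not at all. Between median-of-ratios scaling and total UMIs, the spinal cord median of all genes moved by -0.22 in neutrophil-like and -0.11 in B-like cells on the log2 scale and by under 0.1 in the other classes, and ratios are given on total UMIs. Figures were drawn with matplotlib 3.10.9. Genes of near-identical copies, such as Hspa1a and Hspa1b, Ifit3 and Ifit3b, the H2-Q genes and the histone genes, can share reads, and their values are uncertain to that extent. Single-cell T cell receptor sequences and direct contrasts between tissues were not analysed here.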

Results

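The data are single-cell RNA counts from 6 libraries in 4 groups. Spinal cord leukocytes gave 1 library from mice treated with MOG particles and 1 from mice treated with OVA particles, and lymph node leukocytes gave 2 libraries for each treatment. The study compared the disease antigen (MOG) with an irrelevant antigen (OVA) in each tissue separately, which asks what the antigen in the particles changed in each immune cell type.

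Total UMIs were 87637285 in the spinal cord MOG library (14863 barcodes, median 4433 UMIs) and 73516862 in the spinal cord OVA library (7923 barcodes, median 7617). In lymph node they were 68967988 and 68737840 for MOG replicates 1 and 2 (14686 and 10148 barcodes, medians 1634 and 5092), and 92850117 and 43306962 for OVA replicates 1 and 2 (11802 and 5156 barcodes, medians 5299.5 and 6613). After filtering and doublet removal 12636 and 7126 spinal cord cells were kept from MOG and OVA, and 12288, 8571, 9601 and 4407 lymph node cells from MOG replicates 1 and 2 and OVA replicates 1 and 2. Lymph node MOG replicate 1 stood apart: 30.9% of its barcodes held under 1000 UMIs, against 5.56%, 12.2% and 8.40% in the other lymph node libraries, and 5920 of its 12288 cells (48.2%) fell in clusters that were left unnamed, nearly all made of that library alone. The unnamed shares in the others were 1.09%, 1.42% and 2.16%. The median mitochondrial share of UMIs per barcode was 2.32% and 4.84% in the MOG lymph node libraries and 2.32% and 3.34% in the OVA ones.

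In lymph node, no single gene passed edgeR's main test, which has no replicate block, in any cell class. The groups of genes that camera called were mostly lower after MOG, though none was called with an estimated correlation. Genes of the interferon gamma response, such as the immunity-related GTPases Igtp and Iigp1, were lower in T-like, CD4 T-like and CD8 T-like cells, antigen-presentation genes of MHC class II were lower in dendritic-like cells, and type I interferon genes such as Rsad2 and Isg15 were lower in neutrophil-like cells. Transcripts of the chemokines Xcl1 and Ccl4 stood lower in CD8 T-like cells, while the complement gene C1qa and the ectoenzyme gene Cd38 stood higher in monocyte/macrophage-like cells. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes in each of the 9 classes. At an unadjusted p under 0.05 it counted between 62 of 9591 genes (CD4 T-like) and 684 of 9537 (dendritic-like), and DESeq2 called 11 genes in monocyte/macrophage-like cells, 3 in dendritic-like, 2 in CD8 T-like, 1 in T-like, 1 in neutrophil-like and 0 in the other 4 classes. The share of genes whose MOG and OVA libraries did not overlap ran from 17.2% (T-like) to 26.3% (neutrophil-like) in 8 classes. It was 44.4% in dendritic-like cells. Exchangeable libraries would give 33.3%, but libraries of the same number deviated together, with correlations from 0.221 (dendritic-like) to 0.823 (neutrophil-like). The labels do not pair these libraries. With a replicate block, which treats them as paired, edgeR called from 0 genes (dendritic-like) to 516 (neutrophil-like). With no low-count filter edgeR called up to 51 genes, in monocyte/macrophage-like cells, and without 1 library up to 425, in dendritic-like cells without OVA replicate 1.

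Of 151 pairs of a class and a gene list, camera called 47 (Benjamini-Hochberg within a class), 15 of them higher and 32 lower after MOG. All 47 calls were lost with an estimated correlation, and 11 kept their direction and their call without each library in turn. Among those 11 were the interferon gamma response in T-like, CD4 T-like and CD8 T-like cells, and the type I interferon response in CD8 T-like and neutrophil-like cells. The others were MHC class I in CD8 T-like cells, MHC class II in dendritic-like cells, and neutrophil granule transcripts in CD4 T-like, CD8 T-like, Treg-like and B-like cells.

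CD8 T-like cells (703 and 1291 cells in MOG, 1023 and 645 in OVA) carried less interferon-response RNA after MOG. Xcl1 (ENSMUSG00000026573, chromosome 1, 164931644 to 164935527), the chemokine that draws XCR1-bearing dendritic cells, stood at 17.4 and 26.9 CPM in the MOG libraries and at 99.5 and 100.2 in the OVA libraries. Its log2 fold change was -2.16 ± 0.23 (standard error, n = 2 per group; edgeR adjusted p = 0.116). Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), a chemokine of activated T cells, had -2.07 ± 0.30 (edgeR adjusted p = 0.52). DESeq2 called both. The interferon gamma response list fell by a median of 0.66 on the log2 scale, with 22 of 22 members lower, 10 of them past the threshold when adjusted over the list alone (camera adjusted p = 1.69e-40, and adjusted p = 0.278 with an estimated correlation). Neutrophil granule transcripts, which these cells do not make, fell beside it by a median of 0.69, with 11 of 11 members lower (camera adjusted p = 6.61e-20, and adjusted p = 0.278 with an estimated correlation), at summed levels of 1518 and 757 CPM in MOG and 1680 and 1582 in OVA. The interferon gamma members with the smallest p were the chemokine gene Cxcl10 (-2.15 ± 0.44) and the GTPases Iigp1 (-1.65 ± 0.39), Igtp (-1.05 ± 0.26) and Irgm1 (-0.83 ± 0.24). The type I interferon response list fell by a median of 0.42, with 28 of 29 members lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 1.76e-28, and adjusted p = 0.278 with an estimated correlation). It was led by the antiviral genes Oasl2 (-1.48 ± 0.38), Isg15 (-1.25 ± 0.34), Ifit1 (-0.86 ± 0.25) and Usp18 (-0.68 ± 0.23). MHC class I genes fell by a median of 0.20, with 13 of 16 lower and 0 adjusted over the list alone (camera adjusted p = 7.95e-07, and adjusted p = 0.278 with an estimated correlation). The immunoproteasome subunit Psmb9 had -0.41 ± 0.17, the peptide transporters Tap1 and Tap2 -0.34 ± 0.17 and -0.29 ± 0.17, and the nonclassical H2-T23 -0.34 ± 0.18. Higher in MOG, without passing, were the granzyme gene Gzma (2.18 ± 0.62), the transferrin receptor gene Tfrc (0.60 ± 0.24), the helicase gene Mcm9 (0.62 ± 0.28) and Tmem156 (0.46 ± 0.21), and the inhibitory receptor gene Lag3 had -1.66 ± 0.68 and Ctla4 -0.51 ± 0.59.

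Single libraries moved these medians. For the interferon gamma list in CD8 T-like cells the median was -0.20 without OVA replicate 2 and between -0.98 and -0.58 without each of the others. For the type I list it was -0.26 without MOG replicate 2 and -0.77 without MOG replicate 1.

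**Figure D1:**
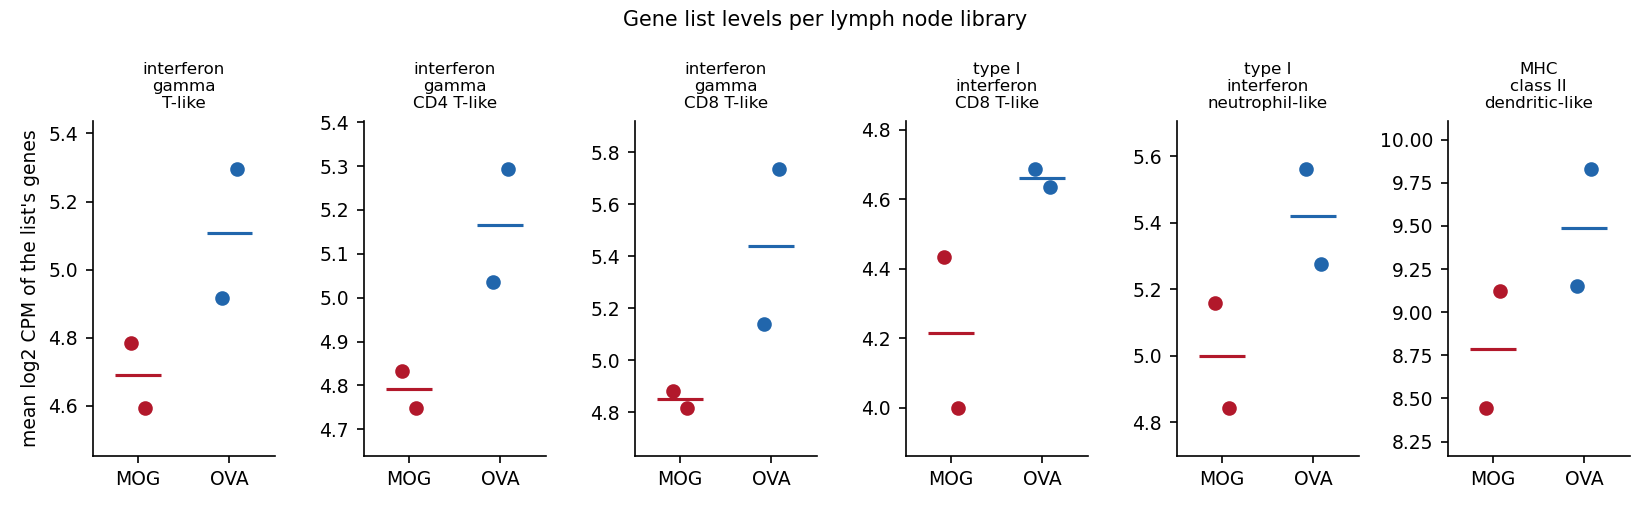
Mean log2 CPM of the genes of 6 class and list pairs (y axes, each with its own range) in the 2 MOG and the 2 OVA lymph node libraries; points are libraries and lines are group means. Both MOG libraries lie below both OVA libraries in each panel, and in CD8 T-like cells the interferon gamma list runs from 4.82 and 4.88 in MOG to 5.14 and 5.74 in OVA. For MHC class II in dendritic-like cells the levels are 8.45 and 9.12 in MOG and 9.15 and 9.83 in OVA. There MOG replicate 2 and OVA replicate 1 nearly meet.

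Over all T-like cells and over CD4 T-like cells the interferon gamma genes were also lower after MOG. The median fell by 0.50 in T-like cells, with 21 of 24 members lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 1.05e-26, and adjusted p = 0.708 with an estimated correlation). Among them were Igtp at -0.80 ± 0.22, Irgm1 at -0.76 ± 0.22, Iigp1 at -1.07 ± 0.32 and the signal transducer Stat1 at -0.68 ± 0.23. In CD4 T-like cells it fell by 0.44, with 20 of 21 lower and 0 adjusted over the list alone (camera adjusted p = 2.92e-16, and adjusted p = 0.451 with an estimated correlation). Members included the guanylate-binding protein Gbp5 at -1.04 ± 0.29, Irgm1 at -0.75 ± 0.24, the transcription factor Irf1 at -0.51 ± 0.18 and Stat1 at -0.55 ± 0.19. Without OVA replicate 2 the T-like median was -0.24. Neutrophil granule transcripts fell beside this list by 0.67 in CD4 T-like cells, with 10 of 10 lower (camera adjusted p = 8.46e-23, and adjusted p = 0.451 with an estimated correlation). Cell cycle genes had a median of 0.32 in T-like cells, with 25 of 25 members higher and 0 adjusted over the list alone (camera adjusted p = 1.23e-08, and adjusted p = 0.708 with an estimated correlation). They included Mki67 (1.17 ± 0.55), Tpx2 (1.06 ± 0.61), Ccnb2 (0.74 ± 0.46) and Rrm2 (0.65 ± 0.43). This direction turned to -0.16 without MOG replicate 2, and the median was 0.09 without OVA replicate 2, 0.85 without MOG replicate 1 and 0.89 without OVA replicate 1. It was -0.09, with the call ended, at clustering resolution 0.5, 0.59 at resolution 2 and 0.66 with the stricter cell filter. T-like clusters without a subtype differed in size: a dividing one held 186 and 75 cells in MOG and 142 and 23 in OVA, and one led by Gzma and Ccl5 held 512 and 11 in MOG and 29 and 28 in OVA. At resolution 0.5, 820 of these 1006 cells lay in the monocyte/macrophage-like class and 183 in the B-like one.

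Among single genes in T-like cells, Xcl1 had -1.97 ± 0.29, the junctional adhesion gene Jaml -0.67 ± 0.16 and the gamma-delta T cell gene Cd163l1 -0.97 ± 0.24. The chemokine gene Ccl1 stood at 0.168 and 0 CPM in MOG and at 2.41 and 51.8 in OVA. Higher in MOG were the histone genes Hist1h2ap (1.05 ± 0.25), Hist1h1b (1.29 ± 0.41) and Hist1h1e (0.78 ± 0.29) and Tfrc (0.64 ± 0.22). The regulatory T cell factor Foxp3 had 0.44 ± 0.32, the cytokine genes Ifng -0.59 ± 0.55 and Csf2 (which encodes GM-CSF) -1.39 ± 0.47, and the inhibitory receptor genes Pdcd1, Lag3 and Ctla4 0.00 ± 0.43, -0.26 ± 0.54 and 0.21 ± 0.40. In CD4 T-like cells the lower genes with the smallest p were the granule genes Ltf (-0.99 ± 0.26) and Retnlg (-0.95 ± 0.26), the orphan receptor gene Gpr83 (-1.05 ± 0.29) and S100a6 (-0.89 ± 0.28). The higher ones were Utp20 (0.79 ± 0.27), Papd5 (0.64 ± 0.25), Zfc3h1 (0.51 ± 0.20) and Alkbh8 (0.64 ± 0.28), and Ctla4 had 0.10 ± 0.50. None of these passed in edgeR.

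Treg-like cells (94 and 245 cells in MOG, 244 and 62 in OVA) made up 6.42% ± 3.01 of T-like cells in MOG and 6.82% ± 3.19 in OVA (SD, n = 2 per group, exact permutation p = 0.667), a difference within the spread between libraries. Without 1 library the difference ran from -2.66 points without OVA replicate 2 to 1.86 without OVA replicate 1. It was 1.80 with the stricter cell filter. The T-like total in MOG replicate 1 is swollen by the 2 clusters without a subtype, and with those left out the shares were 7.56% and 7.22%, a difference of 0.34 points. At clustering resolution 0.5 the class named Treg-like took in all 865 gamma-delta T-like cells (16.5% and 19.7%), so the Treg-like share was not tried there. Their Foxp3 had a log2 fold change of 0.12 ± 0.28, and Ctla4, Lag3 and Pdcd1 had -0.52 ± 0.34, -1.03 ± 0.59 and -0.52 ± 0.57. The Treg list fell by a median of 0.17, with 6 members higher, 12 lower and 0 adjusted over the list alone (camera adjusted p = 0.0442, and adjusted p = 0.872 with an estimated correlation). Members included Gpr83 (-0.65 ± 0.37), the integrin gene Itgae (-0.70 ± 0.49) and the interleukin-2 receptor gene Il2ra (0.37 ± 0.26). Its median was 0.16 without MOG replicate 1, 0.05 without OVA replicate 2 and -0.64 without MOG replicate 2. The call also ended with no low-count filter (-0.09), without doublet removal (-0.16) and at resolution 0.5 (0.17, in the class mixed with gamma-delta cells). In all T-like cells the Treg list was not called (median 0.16, 12 higher and 6 lower, 0 adjusted over the list alone, camera adjusted p = 0.574). Golga3 (1.56 ± 0.43), Xpo4 (1.28 ± 0.40), Plagl2 (1.28 ± 0.41) and Zfp120 (1.14 ± 0.41) stood higher in Treg-like cells, and Retnlg (-1.15 ± 0.29), Stmn1 (-1.25 ± 0.35), Amdhd2 (-1.84 ± 0.56) and Ccdc34 (-1.65 ± 0.51) lower, with none past the threshold. CD8 T-like cells made up 38.6% ± 9.18 of T-like cells in MOG and 42.8% ± 6.66 in OVA (SD, n = 2, exact permutation p = 0.667), a difference that turned to 2.29 points without MOG replicate 1, 0.52 without OVA replicate 2, 1.11 without doublet removal and 1.99 at resolution 0.5, and that came to -10.7 without MOG replicate 2 and -8.91 without OVA replicate 1. With the T-like cells without a subtype left out it turned to 1.79 points (46.8% and 45.0%).

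B-like cells (929 and 1630 cells in MOG, 2056 and 283 in OVA) carried less type I interferon RNA after MOG. That list fell by a median of 0.63, with 26 of 28 members lower and 2 past the threshold adjusted over the list alone (camera adjusted p = 1.81e-19, and adjusted p = 0.629 with an estimated correlation). Isg15 stood at 7.32 and 5.79 CPM in MOG and 39.4 and 12.9 in OVA (-2.15 ± 0.44), and Ifit3b, Mx1 and Rsad2 had -3.36 ± 0.81, -1.31 ± 0.42 and -2.19 ± 0.74. Neutrophil granule transcripts fell beside it by 0.72, with 10 of 10 lower (camera adjusted p = 3.08e-28, and adjusted p = 0.58 with an estimated correlation). The type I call ended without OVA replicate 1, where the median was -7.87e-06, and the median was -0.37 without MOG replicate 2. OVA replicate 1 held 127 of the 147 cells of a B cell cluster led by interferon genes. No gene passed in edgeR, among them Trim41 (0.88 ± 0.27), Stau1 (0.63 ± 0.24), Cspp1 (0.49 ± 0.18) and the centromere gene Hjurp (0.79 ± 0.30), all higher in MOG. Genes for T cell help and restraint showed small values. The ligand genes Cd274 and Pdcd1lg2 had 0.00 ± 0.26 and -0.03 ± 0.30, Cd40 and Cd86 had -0.25 ± 0.20 and -0.16 ± 0.30. Il1b, Tgfb1 and Apoe had 0.24 ± 0.66, -0.03 ± 0.20 and -0.36 ± 0.38.

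Dendritic-like cells (485 and 763 cells in MOG, 460 and 495 in OVA) carried less MHC class II RNA after MOG. The list fell by a median of 0.92, with 11 of 12 members lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 2.36e-05, and adjusted p = 0.788 with an estimated correlation). Its summed levels were 17548 and 31653 CPM in MOG and 31631 and 61624 in OVA. MOG replicate 2 and OVA replicate 1 were thus nearly level. The peptide-loading genes H2-DMb1, H2-DMa and H2-DMb2 had -1.04 ± 0.33, -0.97 ± 0.35 and -0.53 ± 0.21, and the class II chain H2-Aa -0.89 ± 0.39. The C-type lectin genes Cd209d (ENSMUSG00000031495, chromosome 8, 3871824 to 3878555), Mgl2 and Cd209a, markers of lectin-bearing dendritic and myeloid cells, had -2.54 ± 0.25 (59.1 and 50.6 CPM in MOG, 285 and 352 in OVA; edgeR adjusted p = 0.325), -3.07 ± 0.40 and -2.13 ± 0.29. DESeq2 called all 3. Mgl2 and Cd209a are also markers of type 2 conventional dendritic cells (cDC2), and 0 cells were named cDC2 in the main setting. At clustering resolution 2 all 333 cells named cDC2 were monocyte/macrophage-like in the main setting, and at resolution 0.5 425 of 535 were. A change within 1 dendritic type was thus not told apart from the makeup of the class. The interferon-inducible Ifi211 had -1.38 ± 0.23. Higher in MOG without passing were Casz1 (1.85 ± 0.33), Atxn1 (1.82 ± 0.34), Ago3 (1.43 ± 0.28) and the lipid-antigen presenting gene Cd1d1 (1.45 ± 0.30).

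Costimulatory genes in dendritic-like cells were not called (median 0.38, 8 of 10 higher, 0 adjusted over the list alone, camera adjusted p = 0.134). Cd80, Cd86 and the adhesion gene Icam1 had 1.41 ± 0.59, 0.54 ± 0.25 and 0.77 ± 0.38, Cd40 0.17 ± 0.30 and Cd48 -0.60 ± 0.25. Of the inhibitory and tolerance genes, Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), which encodes PD-L1, had 1.48 ± 0.55 (168 and 120.5 CPM in MOG, 80.2 and 22.04 in OVA). Cd200 had 1.19 ± 0.67, Pdcd1lg2 0.13 ± 0.28, Tgfb1 -0.48 ± 0.30 and Entpd1 -0.90 ± 0.45. That list was not called (median -0.06, 7 higher and 7 lower, 0 adjusted over the list alone, camera adjusted p = 0.882). Apoe had -0.92 ± 0.39 and Il1b 0.51 ± 0.56. Cell cycle genes fell by a median of 0.66, with 22 of 25 members lower and 0 adjusted over the list alone (camera adjusted p = 1.37e-05, and adjusted p = 0.788 with an estimated correlation). They included Nusap1 (-0.95 ± 0.30), Stmn1 (-0.70 ± 0.25), Cks1b (-0.73 ± 0.29) and Ccnb2 (-0.73 ± 0.30). The call ended without OVA replicate 2, at a median of -0.17, and the median was -0.995 without OVA replicate 1 and -0.42 and -0.38 at clustering resolutions 0.5 and 2, where 427 and 333 monocyte/macrophage-like cells had joined the class.

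The makeup of the dendritic-like class differed between libraries. Cross-presenting (cDC1) clusters held 19.6% and 37.2% of it in MOG replicates 1 and 2 and 28.5% and 78.6% in OVA replicates 1 and 2 (means 28.4% ± 12.5 and 53.5% ± 35.4, SD, n = 2, exact permutation p = 0.667). Without OVA replicate 2 the cDC1 means were 28.4% and 28.5%. Migratory or mature clusters held 74.8%, 58.5%, 63.5% and 12.5%. Plasmacytoid cells, for which Cd209d is also a marker, held 4.95% ± 0.878 in MOG and 8.47% ± 0.598 in OVA, without overlap (SD, n = 2, exact permutation p = 0.333, the smallest this design can give), and at clustering resolution 0.5, where 110 of these 141 cells fell into another dendritic cluster, they held 1.35% and 1.27%. Neutrophil granule transcripts in the dendritic-like class were not called (median 1.16, 10 of 10 higher, 0 adjusted over the list alone, camera adjusted p = 0.23) and summed to 10141 CPM in MOG replicate 1 against 1056 in MOG replicate 2 and 1839 and 3223 in OVA. The MHC class II median was -0.33 without OVA replicate 2 and -0.57 without MOG replicate 1.

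Monocyte/macrophage-like cells (985 and 1325 cells in MOG, 1844 and 506 in OVA) had no gene past edgeR's threshold. The first genes below have the smallest p among those whose treatments did not overlap, 20.7% of all genes in the class. With 2 libraries per group, ranking by p favours genes whose replicates lie close together. Cd38 (ENSMUSG00000029084, chromosome 5, 43868553 to 43912375) stood at 77.7 and 78.8 CPM in MOG and 34.5 and 35.2 in OVA (1.17 ± 0.16). The lectin receptor gene Clec4n had 1.11 ± 0.16, the chemokine gene Cxcl16 1.08 ± 0.16, and C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803) 1.58 ± 0.28. DESeq2 called these 4 and edgeR did not. Lower were Pdlim1 (-1.03 ± 0.26), Lmo1 (-0.77 ± 0.22), Rdm1 (-0.67 ± 0.22) and the interferon-induced Usp18 (-0.90 ± 0.27). The inflammatory cytokine Il1b had 0.78 ± 0.20 (158 and 127 CPM in MOG, 91.3 and 74.6 in OVA). Its list had a median of 0.10, with 11 members higher, 7 lower and 0 adjusted over the list alone (camera adjusted p = 0.0425, and adjusted p = 0.634 with an estimated correlation). The median was -0.14 without MOG replicate 1, -0.11 without OVA replicate 2, 0.24 without MOG replicate 2 and 0.70 without OVA replicate 1. The inflammatory call ended with no low-count filter (0.20), with the stricter cell filter (0.067) and at resolutions 0.5 (0.17) and 2 (0.070), and the median was 0.27 without doublet removal and 0.21 with library-specific clusters kept. At resolution 0.5 the class held 8580 cells, 3513 of them unnamed and 820 T-like in the main setting. Neutrophil granule transcripts had a median of 1.20 in the same cells (10 of 11 higher, camera adjusted p = 3.33e-05, and adjusted p = 0.634 with an estimated correlation). Other members of the inflammatory list included Ccl7 (2.52 ± 1.13), Nfkbiz (0.30 ± 0.19) and Ccl3 (-0.69 ± 0.73). Cell cycle genes fell by a median of 0.39, with 25 of 25 lower and 0 adjusted over the list alone (camera adjusted p = 4.31e-08, and adjusted p = 0.634 with an estimated correlation). Members included Top2a at -0.55 ± 0.29, Cdk1 at -0.71 ± 0.42, Cenpf at -0.56 ± 0.35 and Ube2c at -0.53 ± 0.35. The median was 0.18 without OVA replicate 1, -0.83 without OVA replicate 2, -0.61 without MOG replicate 1 and -0.25 without MOG replicate 2, and it was -0.26 without doublet removal and -0.22 at resolution 0.5. Cd274, Pdcd1lg2, Cd80, Cd86, Cd40, Tgfb1 and Apoe had log2 fold changes from 0.01 (Cd40 and Tgfb1) to 0.36 (Pdcd1lg2). The MHC class II list was also called in these cells, but not among those kept without each library. Its summed levels overlapped, at 20712 and 29074 CPM in MOG and 15047 and 26958 in OVA.

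**Figure D2:**
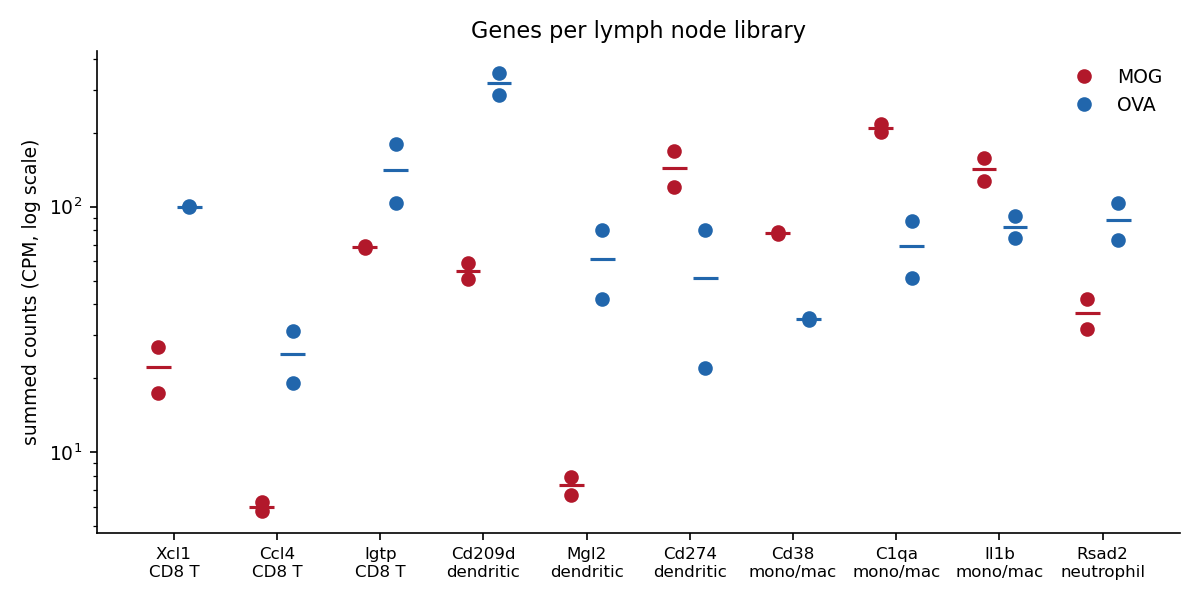
CPM of 10 named genes in the cell class given under each (y axis, log scale), for the 2 MOG and 2 OVA lymph node libraries; points are libraries and lines are group means. The libraries of the treatments do not overlap for any gene shown, and none passed edgeR's adjusted threshold. The rule for named genes asks for such libraries, so the lack of overlap reflects how genes were picked and is not a separate result. Genes without overlap ranged from 17.2% of those tested in T-like cells to 44.4% in dendritic-like cells.

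Neutrophil-like cells (1222 and 1709 cells in MOG, 2089 and 1613 in OVA) carried less type I interferon RNA after MOG. The list fell by a median of 0.37, with 24 of 28 members lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 1.13e-15, and adjusted p = 0.655 with an estimated correlation). The antiviral gene Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452) stood at 42.2 and 31.8 CPM in MOG and 104 and 73.3 in OVA (-1.26 ± 0.26). Isg15, Cmpk2 and Usp18 had -1.25 ± 0.30, -0.80 ± 0.20 and -1.28 ± 0.37. The median was -0.66 without MOG replicate 1. The kinase gene Stk39 had -1.14 ± 0.21. H2-Q7 (1.02 ± 0.24), Spint1 (0.96 ± 0.24), Clec4n (1.22 ± 0.33) and the caspase gene Casp6 (0.89 ± 0.25) stood higher. Il1b, Cd274 and Tgfb1 had -0.04 ± 0.22, 0.33 ± 0.31 and 0.03 ± 0.19. In NK-like cells (101 and 169 cells in MOG, 187 and 57 in OVA) the cytochrome oxidase subunit gene Cox6a2 stood at 0 and 1.09 CPM in MOG and 22.98 and 56.9 in OVA. Cox6a2 is also a marker of plasmacytoid cells, whose share of dendritic-like cells was lower in both MOG libraries. The granzyme gene Gzmm had -2.24 ± 0.63, Cx3cr1 -0.89 ± 0.30 and Psat1 -1.17 ± 0.42. Khdc1a (1.71 ± 0.46), Mut (1.64 ± 0.50), Hjurp (1.25 ± 0.38) and Zfp142 (1.85 ± 0.57) stood higher. None passed.

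RNA of neutrophil granules was lower after MOG in CD4 T-like, CD8 T-like, Treg-like and B-like cells, which do not make it. The granule list fell by a median of 0.67 in CD4 T-like cells (10 of 10 lower, 2 adjusted over the list alone, camera adjusted p = 8.46e-23, and adjusted p = 0.451 with an estimated correlation). It fell by 0.69 in CD8 T-like cells (11 of 11 lower, 1 adjusted over the list alone, camera adjusted p = 6.61e-20, and adjusted p = 0.278 with an estimated correlation). It fell by 0.69 in Treg-like cells (8 of 9 lower, 2 adjusted over the list alone, camera adjusted p = 7.66e-10, and adjusted p = 0.788 with an estimated correlation). In B-like cells it fell by 0.72 (10 of 10 lower, 6 adjusted over the list alone, camera adjusted p = 3.08e-28, and adjusted p = 0.58 with an estimated correlation). The lactoferrin gene Ltf had -0.99 ± 0.26, -1.24 ± 0.32, -0.82 ± 0.44 and -0.94 ± 0.25 in these classes. Ngp and Camp had -0.99 ± 0.20 and -0.77 ± 0.20 in B-like cells. Without doublet removal the B-like call ended at a median of -0.14. The CD4 and CD8 T-like medians were -0.36 and -0.42 without MOG replicate 2 and -1.07 and -1.11 without MOG replicate 1. The B-like median was -0.43 without MOG replicate 2, and the Treg-like one -1.10 without MOG replicate 1. The list was also called lower in T-like cells as a whole (median -0.04, 9 of 11 lower, 0 adjusted over the list alone, camera adjusted p = 0.00317, and adjusted p = 0.708 with an estimated correlation) and in NK-like cells (median -0.43, 7 of 9 lower, 0 adjusted over the list alone, camera adjusted p = 0.00885, and adjusted p = 0.68 with an estimated correlation). There MOG replicate 1 lay above both OVA libraries, at 2763 summed CPM against 1860 and 1850 in T-like cells and 3698 against 2033 and 2269 in NK-like cells. Without MOG replicate 2 the medians turned to 0.51 and 0.40, and without MOG replicate 1 they were -1.15 and -1.11. The T-like call ended without OVA replicate 2 and turned with the stricter cell filter, at 0.76, and the medians were -0.67 and -1.36 without doublet removal. In monocyte/macrophage-like cells the same list had a median of 1.20 (10 of 11 higher, 0 adjusted over the list alone, camera adjusted p = 3.33e-05, and adjusted p = 0.634 with an estimated correlation), where Ngp had 2.14 ± 1.15 and S100a9 1.20 ± 0.62. It turned to -0.57 without MOG replicate 1, was 1.88 without MOG replicate 2, and its call ended at resolution 2 (0.42) and without doublet removal, where the test turned at a median of 0.17.

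Mitochondrially encoded transcripts rose after MOG by medians of 0.16 to 0.41 in 8 of the 9 classes, dendritic-like cells being the exception (camera adjusted p from 3.42e-07 in neutrophil-like to 0.048 in NK-like cells, and adjusted p from 0.379 to 0.872 with an estimated correlation). All 13 members were higher in T-like, CD4 T-like, CD8 T-like and neutrophil-like cells, with 0 adjusted over the list alone. The complex I gene mt-Nd5 had 0.38 ± 0.19 in T-like and 0.33 ± 0.20 in B-like cells. The medians turned negative, between -0.29 and -0.15, without MOG replicate 2 in 7 of these classes and came to 0.11 in neutrophil-like cells. Without OVA replicate 1 they were also negative in 6 classes, down to -0.21 in NK-like cells, and without MOG replicate 1 or OVA replicate 2 they were higher, up to 0.67 in NK-like cells. With the stricter cell filter the call ended in T-like (0.074), CD4 T-like (0.098), CD8 T-like (0.091) and monocyte/macrophage-like (0.12) cells.

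In spinal cord, monocyte/macrophage-like cells carried more inflammatory RNA in the MOG library than in the OVA library and took up a larger share of all cells. The cytokine genes Il1a, Tnf, Il1b and Il6 and the interferon-induced chemokine gene Cxcl9 were higher in them, and the lipid transport gene Apoe was lower. Each treatment has 1 library, so the intervals below count sampling of molecules or cells only and nothing here is a test between treatments. Beyond 2-fold, the MOG library was higher for 62 of 3023 genes and lower for 5 in monocyte/macrophage-like cells, while 2 lymph node libraries of the same treatment differed in this class for 55 (MOG) and 61 (OVA) genes. The counts were 10 and 0 in neutrophil-like cells (same-treatment lymph node pairs 43 and 38), and 9 and 3 in T-like cells (48 and 14). They were 6 and 4 in CD4 T-like cells (17 and 11), 4 and 0 in CD8 T-like cells (18 and 16) and 4 and 8 in B-like cells (20 and 14). Without doublet removal they were 17 and 4 in CD4 T-like and 23 and 0 in CD8 T-like cells. Both totals then exceed those of the lymph node pairs, which were counted in the main setting. Lymph node MOG and OVA libraries that share a replicate number differed for 31 and 9 genes in monocyte/macrophage-like, 19 and 6 in neutrophil-like and 3 and 15 in T-like cells. They differed for 2 and 3 in CD4 T-like, 2 and 8 in CD8 T-like and 2 and 4 in B-like cells.

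Neutrophil-like cells made up 77.9% of the MOG library (95% interval 77.2 to 78.6) and 80.7% of the OVA library (79.8 to 81.6). The gap was wider without doublet removal (68.2% and 82.1%) and at clustering resolutions 0.5 (72.3% and 80.2%) and 2 (64.7% and 78.95%), where 1619, 741 and 1791 neutrophil-like cells fell in clusters left unnamed. Monocyte/macrophage-like cells made up 8.55% (8.07 to 9.06) and 5.08% (4.58 to 5.62), and 38.7% and 26.4% once neutrophil-like cells were left out, an order that turned to 26.0% and 26.5% without doublet removal and to 25.6% and 31.2% at clustering resolution 2, where those unnamed cells stay in the total. T-like cells made up 7.68% (7.23 to 8.16) and 7.93% (7.31 to 8.58), and CD4 T-like cells 4.21% (3.87 to 4.58) and 3.75% (3.32 to 4.21), which turned to 4.23% and 4.50% without doublet removal, where 157 CD8 T-like cells had joined the class. CD8 T-like cells made up 2.75% (2.48 to 3.05) and 3.68% (3.25 to 4.14). Treg-like cells 0.720% (0.580 to 0.883) and 0.505% (0.354 to 0.699), and B-like cells 1.85% (1.62 to 2.10) and 1.45% (1.18 to 1.75). CD8 T-like shares were 1.79% and 2.22% without doublet removal, and the B-like shares were 1.11% and 1.04% with the stricter cell filter.

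**Figure D3:**
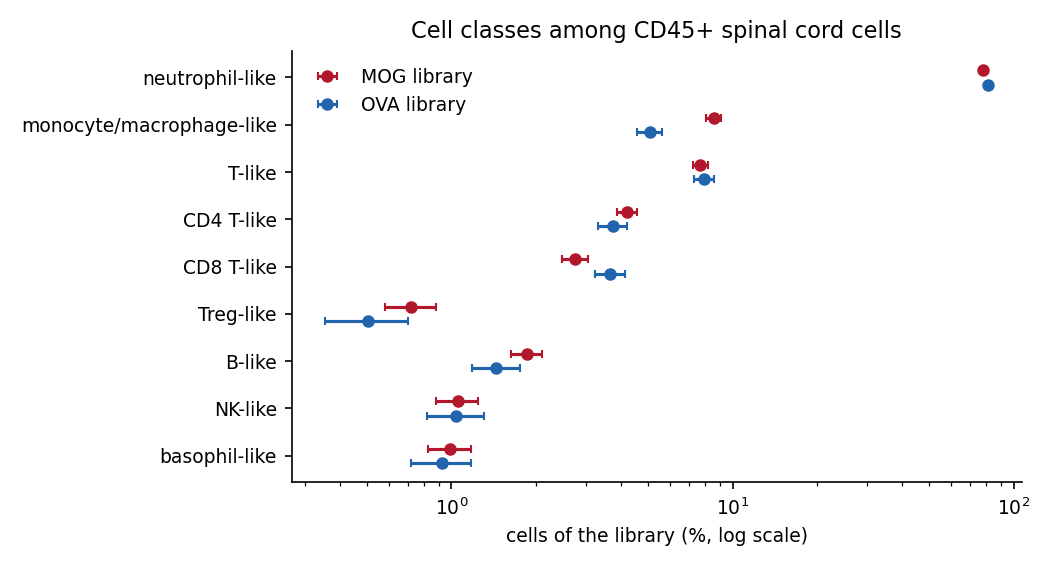
Share of each cell class among CD45+ spinal cord cells (x axis, log scale) in the MOG and OVA libraries, 1 library each; bars are 95% intervals that count sampling of cells only. Monocyte/macrophage-like cells are 8.55% in MOG and 5.08% in OVA.

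Monocyte/macrophage-like cells (1081 cells in MOG, 362 in OVA) had the widest differences. Cluster 10, which held 447 of them in MOG and 213 in OVA, was also counted among the granulocyte precursor clusters described at the end. The inflammatory list had a median log2 ratio of 1.62 (24 of 25 members higher in MOG, 16 beyond 2-fold, above all 10000 random gene sets). Il1a (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972) had 3.17 (2.75 to 3.63), Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) 2.74 (2.54 to 2.96). Il6 had 2.54 (2.28 to 2.81) and Il1b had 2.17 (2.12 to 2.23). The natural antagonist of interleukin-1, Il1rn, was also higher at 2.69 (2.45 to 2.94). So were the transglutaminase gene Tgm2 at 2.80 (2.51 to 3.098), Id3 at 2.73 (2.40 to 3.07) and Sdc4 at 2.76 (2.39 to 3.16). Neutrophil granule transcripts had a median of 0.18 in these cells (8 of 11 higher), or 0.70 (11 of 11) without doublet removal. Interferon gamma response genes had a median of 0.96 (25 of 25 higher), with Gbp5 at 2.62 (2.33 to 2.93), Cxcl9 at 2.32 (2.18 to 2.46), Gbp2 at 2.25 (2.10 to 2.39) and the nitric oxide synthase gene Nos2 at 2.29 (1.964 to 2.63). Lower in MOG were Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) at -1.45 (-1.49 to -1.42) and Rsrp1 at -1.30 (-1.39 to -1.21). So were the heat-shock genes Hspa1a and Hspa1b at -1.84 (-1.97 to -1.70) and -1.62 (-1.84 to -1.41).

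Costimulatory and inhibitory genes were both higher in these cells. Costimulatory genes had a median of 0.98 (6 of 8 higher), or 0.63 without doublet removal, with Cd83 at 1.87 (1.60 to 2.14), Cd40 at 1.81 (1.45 to 2.18), Icam1 at 1.37 (1.16 to 1.57) and Cd86 at 0.35 (0.19 to 0.51). Inhibitory and tolerance genes had a median of 1.07 (14 of 16 higher), with Cd274 at 2.11 (1.84 to 2.39), Pdcd1lg2 at 3.27 (1.65 to 5.59) and Tgfb1 at 0.11 (0.01 to 0.20). The arginase gene Arg1, which is not on that list, had 1.60 (1.27 to 1.95). GM-CSF response genes had a median of 0.52 (12 of 14 higher). The chemokine gene Ccl17 had 3.64 (3.08 to 4.25), or 7.005 at clustering resolution 2, where 55 of these cells were named migratory or mature dendritic, Cish 1.39 (0.92 to 1.89), and Ccl22, with 1 UMI in the OVA library, 7.26 (4.77 to 12.57). Cell cycle genes had a median of -0.20 (23 of 25 lower), among them Ccnb2 at -0.54 (-0.65 to -0.43). MHC class II genes had 0.13 (8 of 11 higher), with H2-Ab1 at 0.31 (0.25 to 0.37). Without doublet removal (0.10) or with the stricter cell filter (0.14) the class II median no longer stood out from random gene sets.

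**Figure D4:**
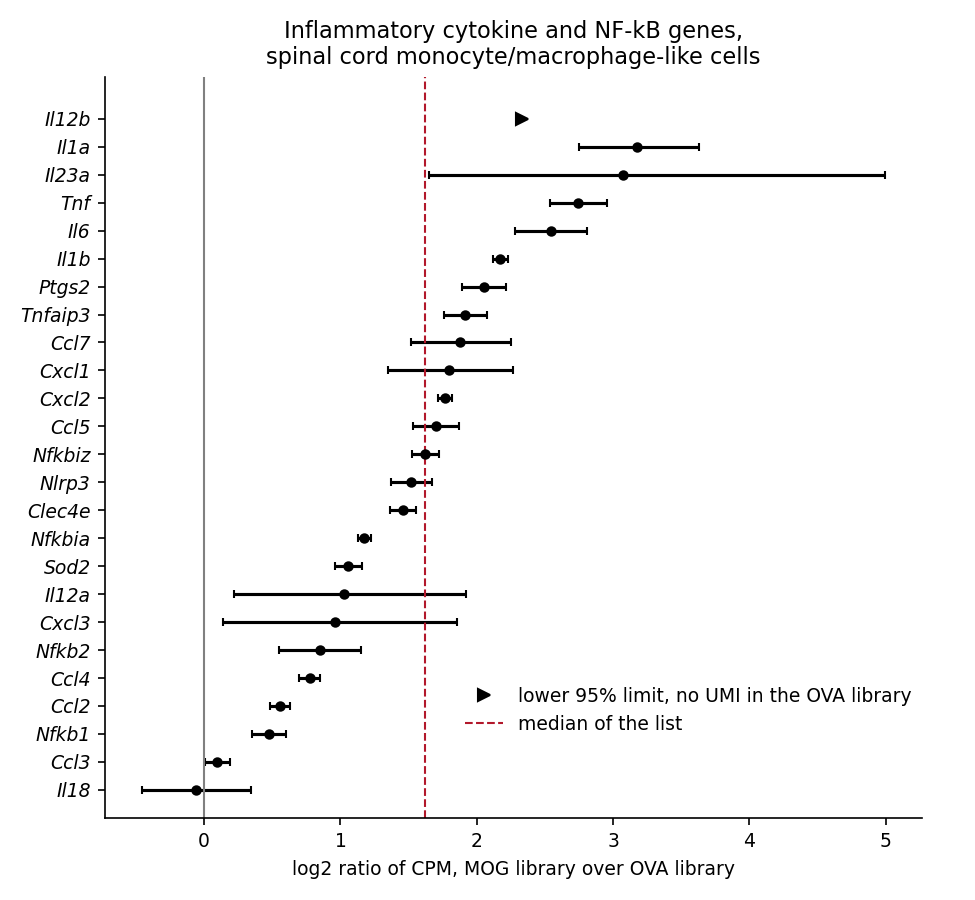
Log2 ratio of CPM, MOG library over OVA library (x axis), for each inflammatory cytokine and NF-kB gene (y axis) in spinal cord monocyte/macrophage-like cells, 1 library per treatment; bars are 95% intervals that count molecules only, the triangle is a lower limit where the OVA library held no UMI, and the dashed line is the median, 1.62. All but 1 of the genes lie above 0.

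Neutrophil-like cells (9844 cells in MOG, 5753 in OVA) were shifted the same way for inflammatory genes, while type I interferon genes had a small median below 0. The inflammatory list had a median of 1.06 (22 of 23 higher), with Il1b at 0.95 (0.93 to 0.96), Il23a at 3.43 (2.69 to 4.27) and Il1a at 2.84 (2.29 to 3.43). Without doublet removal the median was 0.75, Il1b had 0.37, Il23a 2.06 and Nlrp3 0.68, and at clustering resolution 2 Il1b had 0.63. The NF-kB brake Tnfaip3 had 2.11 (2.03 to 2.20), the matrix gene Thbs1 1.76 (1.71 to 1.81) and the inflammasome gene Nlrp3 1.43 (1.34 to 1.51). Interferon gamma response genes had a median of 0.50 (22 of 22 higher), or 0.29 (15 of 22 higher) under median-of-ratios scaling, with Cxcl10 at 1.67 (1.51 to 1.84). Type I interferon genes had a median of -0.17 (18 of 27 lower), with Ifit3 at -1.39 (-1.66 to -1.13) and Usp18 at -0.76 (-1.04 to -0.48), and the median was -0.39 under median-of-ratios scaling and -0.29 without doublet removal. In lymph node neutrophil-like cells the mean log2 levels of this list were 5.16 and 4.84 in MOG and 5.56 and 5.28 in OVA. Libraries of the same treatment thus lay farther apart there than the median of -0.17, though those are means of levels and not medians of ratios. The handling stress list had a median of 0.10 (12 higher and 7 lower) and turned to -0.11 under median-of-ratios scaling and -0.08 without doublet removal, while its members Jun and Fos had -0.84 (-0.90 to -0.79) and -0.64 (-0.66 to -0.62). Cd274 had 1.51 (1.26 to 1.76).

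T-like cells (971 in MOG, 565 in OVA) carried more RNA of activation, regulatory and helper genes in the MOG library. The Treg list had a median of 0.45 (16 of 18 higher), and Th17 genes 0.40 (14 of 16 higher). The medians were 0.45 for inhibitory receptors (15 of 21 higher), 0.41 for activation genes (13 of 16 higher), 0.45 for interferon gamma response genes (19 of 23 higher) and 0.08 for Th1 genes (9 higher and 7 lower), which turned to -0.0027 under median-of-ratios scaling. Libraries of the same treatment also lay apart in lymph node T-like cells. Mean log2 levels of the Treg list were 4.48 and 5.17 in MOG and 4.93 and 4.65 in OVA. Those of Th17 genes were 3.20 and 3.77 in MOG and 3.84 and 3.65 in OVA. These are means of levels, not medians of ratios. Shifts of the size seen here can thus arise between libraries of the same treatment. Handling stress genes were lower, with a median of -0.15 (12 of 19 lower), or -0.23 under median-of-ratios scaling. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) had 1.03 (0.61 to 1.48), Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) 0.96 (0.81 to 1.12). Ifng had 0.85 (0.71 to 0.99), Csf2 0.44 (0.17 to 0.72). Pdcd1 had 1.02 (0.65 to 1.41), Ctla4 0.53 (0.40 to 0.66), Lag3 0.36 (-0.10 to 0.83) and the cytokine Il10 -0.61 (-1.28 to 0.06). Cxcl10, Ccl1, Areg, Nr4a3 and Tnfrsf9 had 1.90 (1.59 to 2.23), 1.68 (1.44 to 1.93), 1.53 (1.36 to 1.70), 1.43 (1.22 to 1.65) and 1.46 (1.18 to 1.75). Hspa1a and Jun had -1.68 (-1.97 to -1.40) and -1.16 (-1.29 to -1.03). In CD4 T-like cells the Th17 list had a median of 0.17 (10 of 16 higher), which did not stand out from random gene sets, or 0.28 (14 of 16 higher) without doublet removal, where it did. Stress genes had one of -0.44 (15 of 19 lower), or -0.21 without doublet removal. Within these cells Ifng and Il17a had 0.93 (0.77 to 1.08) and 0.73 (0.57 to 0.88), Il22 had -1.59 (-2.07 to -1.11) and Ccl3 4.18 (2.92 to 5.83). Cell cycle genes had a median of 1.14 (23 of 24 higher), with Cenpf at 3.20 (1.76 to 5.13) and Birc5 at 1.94 (0.90 to 3.15). Without doublet removal, where 157 of the 950 CD4 T-like cells were CD8 T-like in the main setting, Il22 had -0.13, Il17a 1.16 and Birc5 0.50. Neutrophil granule transcripts had a median of 0.21 in CD4 T-like cells (10 of 11 higher), or 0.78 without doublet removal.

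At 1000 UMIs per cell (9 and 3 cells left out), Foxp3 was seen in 2.70% of T-like cells in MOG (n = 962) and 1.42% in OVA (n = 562), a ratio of 1.90 (95% interval 0.866 to 4.16). Il17a was seen in 5.72% and 3.20%, a ratio of 1.79 (1.06 to 3.01). Ifng was seen in 12.8% and 10.7% (1.20, 0.896 to 1.60), Csf2 in 3.43% and 2.14% (1.61, 0.837 to 3.09). Pdcd1 was seen in 5.51% and 2.31% (2.38, 1.31 to 4.33), Lag3 in 3.33% and 3.20% (1.04, 0.589 to 1.83) and Il10 in 0.624% and 0.712% (0.876, 0.248 to 3.09). Before thinning Pdcd1 was seen in 13.2% and 10.97%, a ratio of 1.20, and at 2000 UMIs its ratio was 1.42 (0.932 to 2.17). The ratio of Csf2 turned to 0.931 and that of Ifng to 0.977 without thinning, where Il10 had 0.504, Foxp3 1.13 and Lag3 0.866. At 500 UMIs Foxp3 turned to 0.840 and Lag3 to 0.509. In B-like cells of equal depth these genes were seen in 0 of 221 cells in MOG, which allows up to 1.36%, and 0 of 101 in OVA, which allows up to 2.97%, except Lag3 in 1 of 101 (0.990%). Median UMIs were 3618 and 5433 in T-like and 2202 and 3570 in B-like cells. In lymph node, where 450 and 9 T-like cells in MOG and 99 and 39 in OVA were left out as too shallow, so that MOG replicate 1 lost 450 of 2190, the same share for Foxp3 was 2.06% ± 0.957 in MOG and 1.44% ± 0.750 in OVA (SD, n = 2, exact permutation p = 0.667), and for Pdcd1 0.883% ± 0.436 and 0.979% ± 0.527.

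CD8 T-like cells (348 in MOG, 262 in OVA) differed from CD4 T-like cells in Ifng, which was lower in the MOG library at -0.80 (-1.22 to -0.39). At clustering resolution 0.5 the CD4 and CD8 T-like cells fell into 1 class, named CD8 T-like, with Ifng at 0.93, so values of CD8 T-like cells were not tried there. Their interferon gamma response genes were higher (median 0.53, 17 of 21), and so were neutrophil granule transcripts, which they do not make (median 0.35, 11 of 11, or 1.46 without doublet removal). The former had Irgm2 at 1.68 (0.86 to 2.57) and Gbp5 at 0.99 (0.22 to 1.79). The cAMP-response gene Crem had 2.23 (1.69 to 2.80), Cxcl10 2.32 (1.59 to 3.12), Vps37b 1.33 (1.19 to 1.48). Nr4a1 had 1.27 (0.96 to 1.57) and Pdcd1 1.25 (0.58 to 1.956). The residency chemokine receptor gene Cxcr6 and Ifitm1 had -1.09 (-1.52 to -0.68) and -1.03 (-1.29 to -0.76).

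B-like cells (234 in MOG, 103 in OVA) held far less RNA of the antibody joining chain Jchain in the MOG library, at -7.03 (-8.25 to -6.05). Ighg2b had -1.91 (-3.29 to -0.69), with a median of -0.41 for germinal center and plasma cell genes (6 of 9 lower). B cell activation genes had a median of 0.56 (11 of 14 higher), with Egr3 at 1.53 (0.81 to 2.31) and Irf4 at 1.23 (0.60 to 1.91). Cd274 had 2.08 (1.04 to 3.28), Ptpn22 1.91 (1.25 to 2.62) and the neutrophil elastase gene Elane 2.76 (1.28 to 4.71). Hspa1b, Hspa1a and Dnajb1 had -4.34 (-6.26 to -2.90), -3.49 (-5.19 to -2.15) and -1.57 (-2.18 to -0.98).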

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

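The test of whether 1 library decides the interferon gamma difference was chosen after that result was seen, and the free RNA test was left undecided on the width of its interval only after its value was seen.

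Genes of the interferon gamma response, such as Igtp and Gbp5, moved in opposite directions in the spinal cord and in lymph node. In T-like cells the median was 0.45 in spinal cord and -0.50 in lymph node, in CD4 T-like cells 0.25 and -0.44, and in CD8 T-like cells 0.53 and -0.66. Neutrophil granule transcripts such as Ltf and Ngp did the same, at 0.21 and -0.67 in CD4 T-like cells and 0.35 and -0.69 in CD8 T-like cells. Without doublet removal the spinal cord medians were 0.78 and 1.46, and the CD4 one was 0.13 under median-of-ratios scaling. Vitamin D response genes, among them Ninj1 and Camp, which is also a neutrophil granule transcript, stood at 0.50 over 4 measured members in spinal cord CD8 T-like cells (1.39 over 3 without doublet removal, rising as granule transcripts did) and -0.24 in lymph node ones (0 of 4 members higher, 0 adjusted over the list alone, camera adjusted p = 0.0146, and adjusted p = 0.379 with an estimated correlation), where the call ended without MOG replicate 2 (-0.37) and without OVA replicate 1 (-0.28), and the median was -0.13 with no low-count filter and -0.41 without OVA replicate 2. These were picked out because the tissues went opposite ways, and the difference between tissues was not tested, since the spinal cord has 1 library per treatment.

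OVA replicate 2 may account for much of the lower interferon gamma response in lymph node CD8 T-like cells, since the median came to -0.20 without that library, while the list stayed lower and called, a call that is lost with an estimated correlation (adjusted p = 0.278). Free RNA from monocytes and macrophages stays open: their markers had a median of -0.27 in CD8 T-like cells, with an interval that spans the value that would have excluded it, and neutrophil granule transcripts stood at -0.69 in the same cells. Less interferon gamma made in the node also stays open, with Ifng at -0.59 in T-like cells, where it stood at 1.18 and 1.05 CPM in MOG and 2.27 and 1.03 in OVA, and at 0.22 in NK-like cells, where it stood at 66.1 and 47.0 CPM in MOG and 53.3 and 40.3 in OVA. The libraries of the treatments overlap in both. The antigen in the particles is the biological explanation the design names, and it cannot be told apart from these with 2 libraries per treatment.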

How the results depend on the processing

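Keeping library-specific clusters, leaving out neutrophil-like cells or T-like cells without a subtype from the totals of shares, and testing the lists with no low-count filter, a stricter cell filter or other clustering resolutions were chosen after seeing the data.

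Of 263 values that answer a comparison, recomputed without leaving out a library, 194 stayed within their spread or within 1.5 times the count, and 69 moved. Of 1905 values for single lymph node genes 1756 kept their direction and their side of the threshold and 111 newly passed it. Of 292 values for lymph node lists 232 were kept, 47 lost the call, 5 gained it and 3 turned. In spinal cord 905 of 1012 gene values and 101 of 106 list values were kept. Without 1 library fewer lymph node values held: 28 of 60 that answer a comparison stayed and 32 moved, and of 132 list values 89 were kept, 11 lost the call and 20 turned. Of 862 gene values 723 were kept and 67 newly passed. These totals include fits identical to the main one, in classes that a setting left unchanged. The cause of a change was not tested unless it is given.

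Of the 47 lymph node list calls, 47 were kept with RLE normalization and with library-specific clusters, 42 at resolution 2, 40 with no low-count filter, 37 without doublet removal, 36 at resolution 0.5, and 28 of the 39 that the stricter cell filter left. Keeping library-specific clusters altered only monocyte/macrophage-like and neutrophil-like cells, so calls in the other classes could not change there. With an estimated correlation 0 were called. Without MOG replicate 1, MOG replicate 2, OVA replicate 1 and OVA replicate 2 in turn, 39, 21, 23 and 35 of the 47 were kept and 5, 11, 14 and 2 turned. The number of lists called, those newly called included, then ran from 51 to 75.

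The edgeR count of 0 genes per class in lymph node became 32 in T-like, 7 in CD4 T-like, 25 in CD8 T-like, 3 in Treg-like, 19 in B-like, 51 in monocyte/macrophage-like, 36 in neutrophil-like and 7 in NK-like cells with no low-count filter. DESeq2 called 1, 2, 3, 11 and 1 in T-like, CD8 T-like, dendritic-like, monocyte/macrophage-like and neutrophil-like cells, the last being Gm19951. Without doublet removal 1 gene was called in B-like cells, Olfm4. Gm19951 and Olfm4 were chosen after their values were seen. Without 1 library the counts ran from 0 to 53 in T-like, 2 to 11 in CD4 T-like, 2 to 19 in CD8 T-like, 2 to 11 in Treg-like, 0 to 26 in B-like, 0 to 425 in dendritic-like, 0 to 56 in monocyte/macrophage-like, 4 to 64 in neutrophil-like and 2 to 10 in NK-like cells, where a lone library is assumed to vary like the other group.

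With the replicate block, which treats libraries of the same number as paired, edgeR called 2, 40, 63, 5, 63, 47, 516 and 6 genes in T-like, CD4 T-like, CD8 T-like, Treg-like, B-like, monocyte/macrophage-like, neutrophil-like and NK-like cells and kept 47 list calls. The labels give the libraries only the number in common, and the data show that libraries of the same number deviate together. In the paired check the correlation between libraries of the same number ran from 0.221 in dendritic-like to 0.823 in neutrophil-like cells.

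Lymph node lists that changed direction without 1 library had medians from -0.16 to 0.89 (T-like cell cycle), -0.64 to 0.16 (Treg list in Treg-like cells), -0.93 to -7.87e-06 (B-like type I interferon, where the test turned and the median did not), and in monocyte/macrophage-like cells -0.14 to 0.70 (inflammatory), -0.83 to 0.18 (cell cycle) and -0.57 to 1.88 (granule). Granule transcripts ran from -1.15 to 0.51 in T-like and -1.11 to 0.40 in NK-like cells. Mitochondrial transcripts ran from -0.15 to 0.51 in T-like, -0.18 to 0.54 in CD4 T-like, -0.21 to 0.53 in CD8 T-like, -0.23 to 0.44 in Treg-like, -0.18 to 0.54 in B-like, -0.29 to 0.54 in monocyte/macrophage-like and -0.29 to 0.67 in NK-like cells. The Treg list in Treg-like cells turned to 0.17 at resolution 0.5, where gamma-delta T-like cells had joined them, the T-like granule list to 0.76 with the stricter filter, and the test of the monocyte/macrophage granule list turned without doublet removal, at a median of 0.17.

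The class named Treg-like at resolution 0.5, 56.9% of it gamma-delta T-like cells, made up 16.5% in MOG and 19.7% in OVA, and the difference ran from -3.14 there to 1.80 points with the stricter filter. The plasmacytoid share differed by 0.0763 points at resolution 0.5 and by -2.66 at resolution 2. In spinal cord without doublet removal, neutrophil-like shares were 68.2% in MOG and 82.1% in OVA, T-like 6.65% and 7.19%, CD8 T-like 1.79% and 2.22%, CD4 T-like 4.50% in OVA and B-like 1.60% in MOG. With the stricter filter neutrophil-like cells were 81.9% in OVA, monocyte/macrophage-like 9.13% in MOG and B-like 1.11% and 1.04%. At resolution 0.5 neutrophil-like cells were 72.3% in MOG and the joined CD4 and CD8 T-like cells, named CD8 T-like there, 6.98% and 7.44%. At resolution 2 neutrophil-like cells were 64.7% and 78.95%, and monocyte/macrophage-like 6.57% in OVA. Leaving out neutrophil-like cells gave 38.7% and 26.4% monocyte/macrophage-like, 34.8% and 41.2% T-like, 8.38% and 7.50% B-like, and 4.76% and 5.39% NK-like, by construction.

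Spinal cord genes beyond 2-fold came to 22 in T-like, 26 in CD4 T-like, 9 in CD8 T-like, 22 in B-like, 114 in monocyte/macrophage-like and 33 in neutrophil-like cells at 10 CPM, where more genes are considered, to 21 in CD4 T-like and 23 in CD8 T-like cells without doublet removal, to 11 in the joined class named CD8 T-like at resolution 0.5 and to 6 in neutrophil-like cells with median-of-ratios scaling. In CD4 T-like cells glycolysis genes turned to 0.10 without doublet removal. At resolution 0.5 the class named CD8 T-like (882 and 530 cells) held all 799 CD4 T-like cells beside the 610 CD8 ones. Its Cxcr6 stood at 0.071, Ifng at 0.93 and Ngp at -0.000858, which differ in sign from CD8 T-like cells alone and do not test them.

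Shares of T-like cells with a UMI moved with depth. Without thinning the lymph node difference was 0.0788 points for Ifng, -0.551 for Csf2, 0.0524 for Il10 (0.0353 at 2000 UMIs) and -0.238 for Lag3. In spinal cord the ratio was 0.840 for Foxp3 and 0.509 for Lag3 at 500 UMIs and 1.20 for Pdcd1 without thinning. Csf2 turned to 0.931 and Ifng to 0.977 without thinning, and Il10 came to 0.504.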

Other observations

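The stress test of the spinal cord inflammatory genes and the free RNA test of the granulocyte precursors were chosen after their results were seen. A first free RNA test, on CPM against T-like cells, had given a value between its bounds, and the bone marrow test was left undecided on its interval only after its value was seen.

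Hypoxia and glycolysis genes were mixed in spinal cord myeloid cells. In monocyte/macrophage-like cells the list had a median of 0.21 (16 of 20 higher in the MOG library), with the vessel growth factor Vegfa at 1.34 (1.01 to 1.69) and the hypoxia factor Hif1a at 0.76 (0.63 to 0.89). In neutrophil-like cells it had -0.09 (13 of 20 lower), or -0.31 under median-of-ratios scaling, with the lactate transporter Slc16a3 at 0.65 (0.62 to 0.68) and the hexokinase Hk2 at -0.44 (-0.53 to -0.35). Basophil-like cells made up 0.989% of the MOG library (125 cells) and 0.926% of the OVA library (66 cells). A cluster with microglia markers, left unnamed, held 0.894% and 1.04%.

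Inflammatory genes such as Il1a, Tnf and Il1b were higher in monocyte/macrophage-like cells of the spinal cord MOG library. A different mix of clusters is argued against as the sole source, since the median was 0.90, 1.27 and 1.44 within clusters 10, 13 and 15 taken alone. Each lies below the class median given above. Cluster 10 held 447 MOG and 213 OVA cells and cluster 15 held 308 and 49, so the mix may add to the class median. Handling stress stays open: its list had a median of 0.00662 in the same cells, with members going both ways, and turned to -0.0132 under median-of-ratios scaling and -0.01 without doublet removal. A difference that any pair of libraries can show also stays open, since lymph node libraries of the same treatment differed by up to 0.425 for these genes. The antigen may be the source, which 1 library per treatment leaves untested.

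Clusters counted as granulocyte precursors, with the granule protease genes Elane, Mpo, Prtn3 and Ctsg, made up 10.6% of MOG and 10.8% of OVA spinal cord cells. They include cluster 10, with 447 MOG and 213 OVA cells, which is named monocyte/macrophage-like. These shares thus count cells given both names, and the tests here were not repeated without them. For these clusters summed together, the ratio of these genes to Retnlg was at least 113 times that in T-like cells. That argues against free RNA, if free RNA keeps its genes in 1 ratio in every type. The same genes describe the clusters, so a raised ratio was favoured by how they were picked, and the test is not independent of that choice. Mature neutrophil genes stood at 0.0624 of their level in neutrophil-like cells outside these clusters. This cannot decide on doublets, since cluster 10 is not neutrophil-like and its cells entered that level. Bone marrow carried into the preparation stays a possible explanation: B lymphocyte precursor genes were seen in 0 of 322 spinal cord B-like cells, those with at least 1000 UMIs, each thinned to 1000, which allows up to 0.932%. No biological explanation was tested.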
